A study of Oryza sativa with 52 samples.

How the data were processed

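Total RNA from 52 rice leaf samples was measured on 26 two-channel Agilent arrays, 1 sample per channel, 26 labelled with Cy3 and 26 with Cy5. Per the labels, RNA was extracted with a Promega Maxwell 16 instrument, and 200 ng of total RNA was reverse-transcribed, labelled with the Low Input Quick Amp kit and purified on RNeasy columns. Scans were read by the authors with Agilent Feature Extraction 10.5.1.1, and the array files they deposited give the intensity of each spot and of its local background in each channel. Per the file headers, the unit of these signals is scanner intensity, before and after the extraction software's own background subtraction and dye correction (processed signal). The array holds 156732 spots, 4854 of them controls, and 151878 probes of 60 bases. The deposited value table of the authors gives log2 values for 125722 of these probes. Its values had the same distribution in every sample (medians of 5.76 to 5.77) and ranked the probes of a sample as the processed signal did (Spearman correlation of 1 in every sample), so quantile normalisation of the log2 processed signal was inferred. The labels name the affy package, whose version is not given in the sources used here.

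The raw spot intensities were used for the main results. Background was subtracted with the normexp method (offset of 50), arrays were normalised within by loess with control spots weighted 0, and between by quantiles of the average intensity, with limma 3.58.1 in R 4.3.3. Input was read with the data.table package (version 1.17.8), and overlaps and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probes of identical sequence were averaged to 148841, 2005 with a spot the extraction software had marked as faulty in any sample were left out, and a probe was kept when its signal was well above background in at least 4 of the 52 samples, which left 95124. Probes of the same strand that shared a run of at least 30 bases were joined, and the brightest probe stood for each such target, which gave 65597 targets. Quantile normalisation assumes that the samples share 1 distribution of signals, so a change in most transcripts at once would be hidden.

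In each sample 49.2 to 60.8% of the probes were well above background. Median spot intensities ran from 69.9 to 209, local background medians from 17 to 71, and 1 to 137 spots of a sample were marked as faulty. Identical probes printed on 2 spots had a median SD of 0.06 (log2) within a sample, against a residual SD of 0.16 between samples in the fit. Signals near background are compressed by the offset, so differences that rest on them depend on the background treatment. A fold against samples of which none was well above background is given as a lower bound, and for other dim probes the number of samples well above background is given.

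Channels were analysed as separate samples with the array as a block (correlation of 0.513 within an array, estimated from 3000 targets). The model held the 4 series, the 13 sampling times and the dye, with 35 residual degrees of freedom, and was fitted to all 52 samples together. Sampling time served as the block that paired the series. The contrasts were 24 April minus 14 May transplanting, July minus June sampling, their interaction and the second minus the first 10:00. Time of day was tested by an F test over the 13 times. For the shape of the daily profile, cosine and sine terms of 24 h were added for transplanting date and sampling date, and each pair of terms was tested by an F test. All these are the moderated tests of limma, two-sided where signed, with Benjamini-Hochberg adjustment over the 65597 targets and a threshold of 0.05. Peak hours were taken from the means of the 12 clock hours, and shifts and amplitudes from a 24-h cosine fitted to each series. Samples lay on 8 slides, of which 3 held samples of more than 1 series, and 6 samples of the 48-day series had been scanned on later days than the rest.

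The comparisons, their tests, the alternatives and the rule for naming were chosen before the data were examined. Lists of rice genes had been fixed as well, but gene names for the probes were not used here, so no list was tested and the condition on described proteins could not be applied. By the rule, probes could be named as the 8 with the highest and the 8 with the lowest differences by transplanting and by sampling date that had the same sign in both parts, the 10 with the widest range over the day, and the 4 with the smallest p for the interaction, each profile test and the second 10:00; the first 1 to 2 in each direction are printed. Since gene descriptions were lacking, the rule was applied to targets in place of genes. The meaning of the probe name prefixes is not given in the sources used here.

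Tests on simulated data with the same arrays and 200 changed targets per comparison recovered 100% of transplanting differences of 1 log2 unit, 92% of interactions and 94% of second 10:00 differences of that size; at 0.25 log2 units the shares were 78%, 18% and 18%. Between 4.08 and 8.50% of the simulated calls were false. The simulation held array offsets but no slide offsets and no offsets of a whole series, and its targets varied independently. The false share among the real calls can therefore not be read from it. Alternatives tried were the processed signals, quantile normalisation without loess, scaling to the 75th percentile, the authors' table, other filters, the mean of the probes of a target, samples taken as independent, the slide as a fixed or random block, no dye term, no sampling time term, 24-h and 12-h cosines, each series left out, each date alone, and the second 10:00 left out. Alternatives added after the data had been seen were every probe ungrouped, the scan day as a block, the main scan day alone, and array and slide both as random blocks. The comparison of peak hours with each series left out, and the intervals from leaving out each sampling time, were also added after the data had been seen.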

Results

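Leaf gene expression was followed through a day in a paddy field at Toyama, Japan, in 2014. The plants were rice (Oryza sativa) of the variety Koshihikari, transplanted on 24 April or 14 May. Leaves of both plantings were harvested every 2 h from 10:00 to 10:00 of the next day, on 24 to 25 June and again on 1 to 2 July. The 4 series held 13 samples each, 52 in all. Plants were 61 and 41 days past transplanting in June, and 68 and 48 days in July. Each series gave 1 sample per sampling time, so the 4 series served as the replicates of a time (n = 4) and there was no replicate within a series. The 2 series of a sampling date were harvested on the same days. They shared the conditions of each hour and were not fully independent replicates. A mean of 13 samples was behind each series value. RNA levels were read on custom arrays of 60-base probes, on which 49.2 to 60.8% of the probes of a sample were well above local background (median 55.4%) and no probe was saturated. The signals are scanner intensities and not counts of molecules. Probes were grouped by shared sequence into 65597 targets, each represented by its brightest probe. Targets are named by probe identifier and sequence, since the assignment of probes to genes was not analysed here.

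The first question, given by the study's subject of diurnal variation, was which transcripts changed over the day. Most targets did. Signals of 55776 of the 65597 targets (85.0%) differed between sampling times, and for 24929 (38.0%) the highest and lowest time means were at least 1 log2 unit apart. Without a filter on dim probes, 55.1% of 105459 targets differed. Targets were joined by overlapping probe sequence only, so several may come from the same transcript. A range of at least 10-fold was seen for 2157 targets (3.29%). Of the 24929 targets with the wider range, 5477 (22.0%) had their highest mean at 06:00 and 9925 (39.8%) between 04:00 and 08:00. A second broad group of 9218 targets (37.0%) peaked between 16:00 and 22:00. Peaks between 10:00 and 14:00 were seen for 4276 targets (17.2%), and peaks at 00:00 or 02:00 for 1510 (6.06%). The lowest means lay most often at 06:00 as well (4826 targets) and at 08:00 (3965 targets). The share of targets with a range of at least 1 depended on the treatment of dim signals: it was 57.3% with the processed signals, 58.1% of 56656 targets with the authors' table, and 23.6% of 105459 targets without a filter on dim probes, against 38.0% here.

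**Figure D1:**
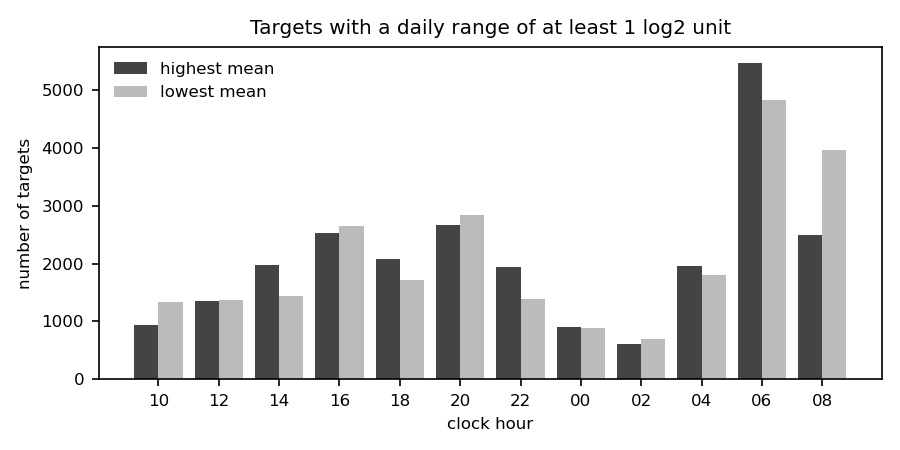
Number of targets (vertical axis) by the clock hour of their highest mean (dark bars) and lowest mean (light bars), for the 24929 targets with a daily range of at least 1 log2 unit, both 10:00 samplings averaged. The tallest bars are those of 06:00, with 5477 peaks and 4826 lowest means, and the fewest peaks fall at 02:00 (614 targets).

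The targets with the widest daily range included 1 set high at 06:00 and another high at 16:00. Among the 10 widest, others peaked at 02:00 and at 00:00. The probe 44kb3_11643 (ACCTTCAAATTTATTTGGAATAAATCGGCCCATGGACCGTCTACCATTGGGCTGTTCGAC) averaged 16.74 ± 0.20 (log2, SD, n = 4) at 06:00 and 6.94 ± 0.39 at 18:00, a range of 9.80 (adjusted p = 4.3e-29, limma; 11.22 with the processed signals). The probe 44kb3_960 (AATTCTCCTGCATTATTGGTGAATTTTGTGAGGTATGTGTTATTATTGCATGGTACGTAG) averaged 16.66 ± 0.15 at 06:00 and 6.90 ± 0.46 at 18:00, a range of 9.76 (11.23 with the processed signals). At 18:00 both were well above background in 3 of the 4 series. In the opposite sense, eAry1_38736 (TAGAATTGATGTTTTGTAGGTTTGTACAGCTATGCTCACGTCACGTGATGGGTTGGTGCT) averaged 15.08 ± 0.71 at 16:00, while its signal at 06:00 was not well above background in any of the 4 series. Its level at 16:00 was therefore at least 374-fold higher (adjusted p = 4.6e-28, limma), a bound taken against the lowest signal of any probe well above background in the same samples, or its own signal where that was higher. The probe eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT) averaged 17.80 ± 0.20 at 16:00 and 9.23 ± 0.96 at 06:00, a range of 8.57 (adjusted p = 7.9e-17, limma).

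Peak hours recurred between series. When each series was left out in turn and targets with a range of at least 1 were chosen on the other 3 (25662 to 26840 targets), 83.3 to 84.8% of them peaked in the series left out within 1 sampling of the peak of the others. Unrelated peak hours would give 27.9 to 28.5%, and targets are not independent replicates. The series left out always shared its days of harvest with another that was kept, so the recurrence is not one between separate days only. The first principal component of all targets held 42.6% of the variance and the second 28.8%, and in both the samples followed the order of the clock in each series. The third component (5.84%) ordered the series by days past transplanting. Its mean score was 47.60 ± 16.1 (SD, n = 13) at 41 days, -0.804 ± 7.34 at 48 days, -9.91 ± 7.48 at 61 days and -36.9 ± 12.6 at 68 days. Each sampling time held the same number of samples of each dye, and of the pairs of neighbouring samplings within a series, 24 shared an array and 24 did not, which the fit took into account.

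**Figure D2:**
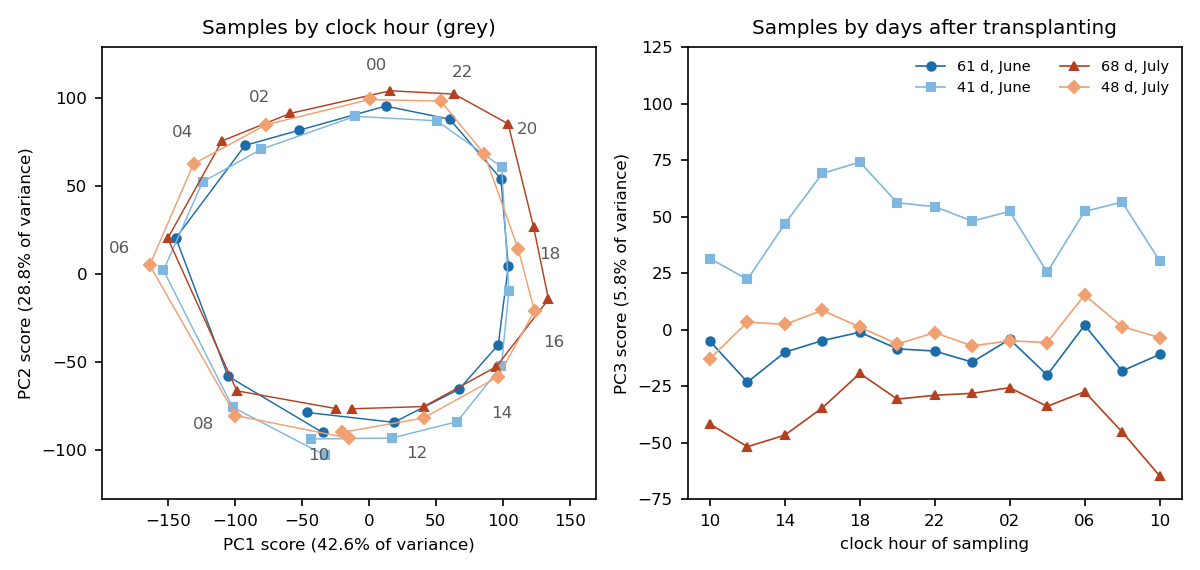
Principal component scores of the 52 samples, with the first component (42.6% of variance) against the second (28.8%) on the left and the third (5.84%) against the clock hour of sampling on the right, 1 symbol per series. The samples run round the left plot in order of the clock hour, and on the right the samples at 41 days lie above all others while those at 68 days lie lowest at each sampling (means 47.60 and -36.9).

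The next question was how the date of transplanting, and with it 20 days of plant age on the day of sampling, affected the level of each transcript. Plants transplanted on 24 April differed from those of 14 May in 25251 targets (38.5%), of which 14550 were higher and 10701 lower with the earlier date. The differences were mostly small, with a median size of 0.20 (log2) among them, and only 93 targets were at least 2-fold higher and 100 at least 2-fold lower. The probe 44kb3_20027 (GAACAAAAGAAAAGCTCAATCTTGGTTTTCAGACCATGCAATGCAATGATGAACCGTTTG) was higher by 2.68 ± 0.16 (log2, SE; adjusted p = 2.3e-15, limma) with 24 April transplanting, and 44kb3_23620 (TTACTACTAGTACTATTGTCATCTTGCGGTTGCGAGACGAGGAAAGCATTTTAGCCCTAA) by 2.48 ± 0.10 (adjusted p = 7.0e-21). Both were higher in 26 of the 26 pairs of samples taken at the same time. The probe eAry2_25535 (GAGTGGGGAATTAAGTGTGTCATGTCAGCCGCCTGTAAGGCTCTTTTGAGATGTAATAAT) was lower, with a difference of -2.71 ± 0.19 (adjusted p = 5.1e-14, limma), and was higher with 24 April in only 2 of the 26 pairs. The probe eAry1_14756 (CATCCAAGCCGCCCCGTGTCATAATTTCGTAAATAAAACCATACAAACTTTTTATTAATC) differed by -2.56 ± 0.19 (adjusted p = 4.1e-13, limma) and was higher in 1 of the 26 pairs. Its difference was -4.01 ± 0.27 in June and -1.11 ± 0.27 in July (interaction of 2.90, adjusted p = 2.0e-06, limma). It was well above background in 8 of 13 samples at 61 days and 10 of 13 at 68 days, and differed by -3.53 with the processed signals.

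The direction of the transplanting difference varied with the hour at which a target peaked. Of the targets peaking at 20:00, 988 were higher and 324 lower with 24 April transplanting, so that 75.3% of those that differed were higher. Of the targets peaking at 06:00, 694 were higher and 1788 lower. Targets peaking at 08:00 went the same way as those of 06:00, with 336 higher and 801 lower, and those of 10:00 too, with 92 higher and 325 lower. Targets peaking at 04:00 did not, with 697 higher and 222 lower. Among the 40668 targets that did not both change over the day and have a range of at least 1, 9067 were higher and 5318 lower.

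**Figure D3:**
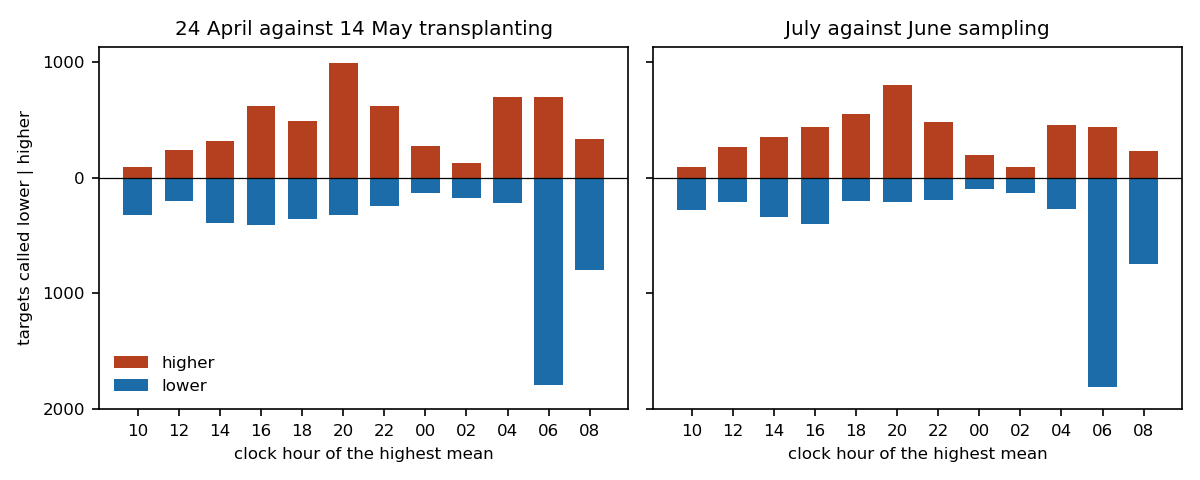
Number of targets that were higher (above 0) or lower (below 0) with 24 April transplanting (left) and in July (right), by the clock hour of the highest mean, for targets with a daily range of at least 1 log2 unit. Targets peaking at 20:00 were mostly higher (988 against 324 by transplanting, 799 against 213 by sampling date), and those peaking at 06:00 mostly lower (694 against 1788, and 436 against 1812).

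Taken by sampling date, as contrasts of the same fit to all 52 samples, 21572 targets differed between 61 and 41 days in June (12037 higher and 9535 lower) and 14149 between 68 and 48 days in July (8284 higher and 5865 lower). Of the 7390 targets that differed on both dates, 6797 (92.0%) did so in the same direction. Across targets, which are not independent replicates, the June and July differences had a Pearson correlation of 0.384, against 0.04 in data simulated without any difference. The simulated targets varied independently, so that value is no measure of chance among targets that vary together. Under scaling of each sample to its 75th percentile in place of quantile normalisation, 32.9% of the differing targets were higher against 57.6% here, so the balance of higher and lower targets rested on the normalisation. Each combination of dates was a single series of harvests, so these tests measured the spread between harvests and not between plots, and with the slide as a fixed block, which left few comparisons within slides, 91 targets differed, the 4 probes above among them.

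Sampling date was compared next, with July plants 1 week older than June plants and harvested under the conditions of another day. Between July and June 20112 targets differed (30.7%), 10234 higher and 9878 lower in July, with a median size of 0.21 (log2) among them. At least 2-fold differences were seen for 70 targets higher and 62 lower. The probe eAry1_20479 (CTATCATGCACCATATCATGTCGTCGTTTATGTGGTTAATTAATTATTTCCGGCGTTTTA) was higher in July by 1.98 ± 0.13 (log2, SE; adjusted p = 3.0e-14, limma), in 26 of the 26 pairs. At 41 days it was well above background in only 5 of 13 samples, so the size of its difference rests partly on signals near background and was 2.99 with the processed signals. The probe eAry2_23284 (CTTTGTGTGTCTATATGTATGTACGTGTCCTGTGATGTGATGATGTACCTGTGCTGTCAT) was higher by 2.06 ± 0.45 (adjusted p = 0.000516), in 22 of the 26 pairs. Lower signals came from eAry1_24410 (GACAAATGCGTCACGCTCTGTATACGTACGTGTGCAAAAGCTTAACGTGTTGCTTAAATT), with a difference of -2.80 ± 0.61 (adjusted p = 0.000582, limma), and from 44kb3_37338 (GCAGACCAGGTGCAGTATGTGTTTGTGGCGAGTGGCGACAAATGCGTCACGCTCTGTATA), with -2.60 ± 0.67 (adjusted p = 0.0027); each was higher in July in 4 of the 26 pairs. The end of the second of these sequences overlaps the start of the first, so the pair does not stand for separate measurements. In July both were dim for part of the day, well above background in 6 and 9 of 13 samples at 68 days and in 10 and 12 at 48 days, and the sizes of their differences, which rest partly on signals near background, were -3.96 and -3.40 with the processed signals.

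As with transplanting, the direction followed the hour of the peak. Of targets peaking at 20:00, 799 were higher and 213 lower in July (79.0% higher), and of those peaking at 06:00, 436 were higher and 1812 lower. The difference from June to July went the same way as that from the later to the earlier planting. Of the 11572 targets that differed in both comparisons, 10920 (94.4%) did so in the same direction. Of these, 5911 were higher in both, where 2270 would be shared if targets were independent, and 5009 lower in both, where 1611 would be. The correlation of the differences across targets was 0.629, against 0.0018 in data simulated without any difference. Simulated targets varied independently, here and in the next comparison, so such values are no measure of chance among targets that vary together. As contrasts of the fit to all 52 samples, 10468 targets differed between dates in the 24 April planting (5163 higher, 5305 lower) and 18599 in the 14 May planting (9344 higher, 9255 lower). The 4830 targets that differed in both plantings had the same direction in 4291 (88.8%), with a correlation of 0.303 across all targets against 0.083 in simulated data. Under 75th percentile scaling 26.2% of the differing targets were higher against 50.9% here. Age and the conditions of the days of sampling differed together and were not separable, and with the slide as a fixed block 339 targets differed and the correlation of both differences was -0.341. None of the 4 probes above then passed the threshold, although their differences were not smaller (2.51 for eAry1_20479, 4.07 for eAry2_23284, -5.83 for eAry1_24410 and -4.60 for 44kb3_37338), with standard errors over all targets 5.50 times as large at the median.

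Whether the transplanting difference itself changed from June to July was tested by an interaction. It did for 7016 targets (10.7%), of which 3232 had a more positive difference in July and 3784 a more negative one. For eAry2_25535 (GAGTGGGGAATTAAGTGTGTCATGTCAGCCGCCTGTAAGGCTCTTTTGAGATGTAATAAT) the 24 April minus 14 May difference was -4.66 ± 0.26 (log2, SE) in June and -0.75 ± 0.26 in July, an interaction of 3.91 ± 0.36 (adjusted p = 1.2e-08, limma). The 14 May plants of June stood apart for this probe, with a mean of 12.90 against 8.27 at 61 days, 8.59 at 68 days and 9.35 at 48 days (n = 13 each). For eAry2_34341 (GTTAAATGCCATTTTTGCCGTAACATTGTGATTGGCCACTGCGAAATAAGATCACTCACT) the difference was 0.61 ± 0.13 in June and -1.39 ± 0.13 in July, an interaction of -2.01 ± 0.19 (adjusted p = 1.2e-08, limma; -2.60 with the processed signals). Leaving the sampling time out of the model, so that the samples were not paired by time, left 143 targets, and the slide as a fixed block left 606.

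**Figure D4:**
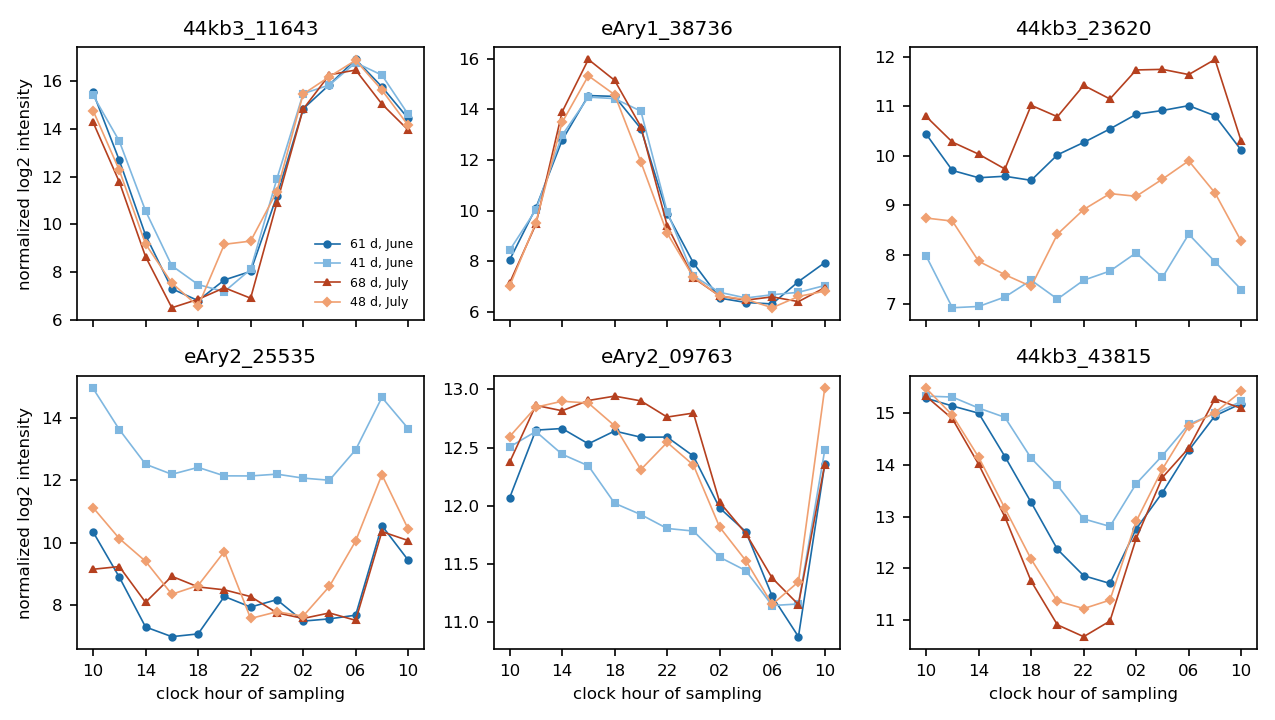
Normalised log2 intensity (vertical axes) against clock hour of sampling for 6 probes, 1 line and symbol per series and 1 sample per point. The probe 44kb3_11643 peaks at 06:00 and eAry1_38736 at 16:00 in all series, 44kb3_23620 is higher in both 24 April series, eAry2_25535 is highest at 41 days (mean 12.90), eAry2_09763 falls later in the day with 24 April transplanting, and 44kb3_43815 falls further and earlier in July.

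The shape of the daily profile was compared with 24-h cosine terms. Profiles differed by transplanting date for 4362 targets and by sampling date for 7139, and 1075 targets did so in both tests, where 475 would be shared if targets were independent. Among targets with a range of at least 1, 2781 (11.2%) had profiles that differed by transplanting date; of these 2375 peaked later and 406 earlier with 24 April transplanting, with a median shift of 1.14 h. The amplitude was smaller in 1960 and larger in 821 (median ratio 0.883). By sampling date, 4885 (19.6%) differed; 4045 of them peaked earlier and 840 later in July (median shift -0.947 h), and the amplitude was larger in 3740 and smaller in 1145 (median ratio 1.19). Over all 24929 targets with a range of at least 1 the shifts were smaller, with a median of 0.298 h by transplanting (17349 later, 7580 earlier; amplitude ratio 0.953) and of -0.404 h by sampling date (6875 later, 18054 earlier; amplitude ratio 1.06). In the targets that differed, the shift by transplanting had a median of 1.27 h in June and 0.957 h in July, and that by sampling date -0.948 h with 24 April and -0.921 h with 14 May transplanting. Profile differences by transplanting were most frequent among targets peaking at 12:00 (36.7%) and 14:00 (28.9%), against 5.49 to 11.9% in the other classes. The shifts are those of the fitted 24-h cosine, whose peak need not be the hour of the highest mean. For eAry2_09763, described next, the highest mean was at 12:00, before all of its fitted peaks.

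The cosine fitted to eAry2_09763 (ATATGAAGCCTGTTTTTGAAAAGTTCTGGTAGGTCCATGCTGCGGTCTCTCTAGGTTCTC) peaked at 17.7 h at both 61 and 68 days and at 14.7 and 15.9 h at 41 and 48 days (adjusted p = 0.000358, limma). That of eAry1_40045 (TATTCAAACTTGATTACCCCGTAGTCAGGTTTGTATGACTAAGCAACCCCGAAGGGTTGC) peaked at 16.94 and 16.89 h at 61 and 68 days and at 14.9 and 15.6 h at 41 and 48 days (adjusted p = 0.000358). By sampling date, 44kb3_43815 (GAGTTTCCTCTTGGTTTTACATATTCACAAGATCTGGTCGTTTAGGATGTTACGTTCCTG) had its fitted peak at 10.8 and 11.1 h in June (61 and 41 days) and at 9.45 and 9.40 h in July (68 and 48 days), with peak-to-trough amplitudes of 3.436 and 2.304 (log2) in June and 4.56 and 4.18 in July (adjusted p = 4.7e-12, limma). With the slide as a fixed block, 0 targets had a profile difference by transplanting at the adjusted threshold (limma; 8309 at an unadjusted p under 0.05; adjusted p = 0.066 for eAry2_09763 and 0.076 for eAry1_40045) and 2266 had one by sampling date. Treating samples of an array as independent raised the counts to 15116 and 18505, and without the samples of later scan days they were 2178 and 3092.

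**Figure D5:**
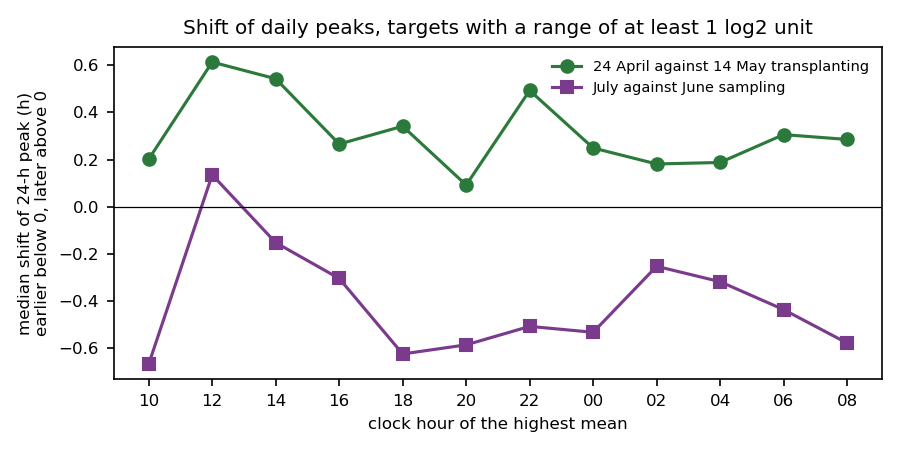
Median shift of the fitted 24-h peak in hours (vertical axis; later above 0, earlier below 0) by the clock hour of the highest mean, for the 24929 targets with a daily range of at least 1 log2 unit, by transplanting date (circles) and sampling date (squares). The shift with 24 April transplanting lies above 0 in every class and is largest at 12:00 (0.613 h), and the July shift lies below 0 in every class but that of 12:00 (0.136 h).

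The 10:00 sampling was taken on both days of each series, which asks how far a clock time repeats after 24 h. Between the second and the first 10:00, 4590 targets differed (7.00%), 2699 higher and 1891 lower on the second day, and 70 and 29 of them at least 2-fold. The probe eAry1_32616 (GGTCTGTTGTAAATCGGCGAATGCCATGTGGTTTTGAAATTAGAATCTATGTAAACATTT) was lower on the second day by a difference of -1.73 ± 0.16 (log2, SE; adjusted p = 1.0e-08, limma), in 4 of 4 series. The probe eAry2_18260 (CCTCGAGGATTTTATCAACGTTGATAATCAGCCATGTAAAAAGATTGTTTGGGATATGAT) differed by -1.52 ± 0.17 (adjusted p = 1.1e-06, limma), and eAry1_01294 (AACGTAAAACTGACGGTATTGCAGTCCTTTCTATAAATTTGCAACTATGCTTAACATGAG), a weak probe well above background in 29 of 52 samples, was higher by 0.93 ± 0.11 (adjusted p = 3.4e-06, limma) in 4 of 4 series. The size of this last difference rests on dim signals, and was 1.82 with the processed signals and 1.87 with the authors' table. Targets peaking at 18:00 were mostly higher on the second day (232 against 20), and so were those peaking at 08:00 (303 against 56), while those peaking at 20:00 were mostly lower (75 against 181). The differences of separate series had correlations across targets from -0.083 to 0.202. On each date the second 10:00 of the earlier planting shared an array with the first 10:00 of the later planting. An array offset would enter the differences of these 2 series with opposite signs and lower their correlation (0.154 in June and -0.083 in July). The correlation to be expected without any change was not estimated, so how much the series had in common cannot be judged from these values. Without the 41-day series 1226 targets differed and without the 68-day series 800; with the slide as a fixed block 21 did, eAry2_18260 not among them (-1.47, adjusted p = 0.061, limma), and under 75th percentile scaling 2446, of which 48.4% were higher against 58.8% here.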

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

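Of the tests in this part, those of scan day and slide for the interaction, of normalisation, of plant age and of a July clock offset for the daily profiles were chosen after the results had been seen.

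The test of the difference between sampling dates singled out the interaction, by which the transplanting difference of 7016 targets was not the same in June and July. Of 100 regroupings of the samples, only the real 1 gave as many, and the highest count of the others was 6. These exchanged the transplanting labels time by time and so mixed the series. A chance offset of 1 whole series is therefore not excluded. Without the 6 samples of the 48-day series that were scanned later, 4926 targets passed the threshold, 4377 of them among the 7016. Later scanning is therefore argued against as the whole cause. The interaction estimates with and without those samples correlated at 0.965 across targets, although both fits share most of their samples. Slide offsets are argued against as the whole cause, since 606 targets passed the threshold with the slide as a fixed block, with standard errors 1.81 times as large. Of the 7016 targets, 95.1% then kept their direction, although they were chosen without the slide in the model and on the same samples. A candidate explanation is that age past transplanting and the day of sampling acted together on these targets, a hypothesis that the single series per combination leaves untested.

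The daily profile of 4362 targets differed by transplanting date and that of 7139 by sampling date, each singled out because the test compared the profiles between groups. For both, 1 of the 100 regroupings, the real 1, gave as many, and the highest of the others was 12 by transplanting and 605 by sampling date. These regroupings also exchanged labels time by time, so a chance difference in the daily course of a whole series is not excluded.

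Fitted 24-h peaks were later with 24 April transplanting and earlier in July. Normalisation is argued against, since over 4 other normalisations at least 82.9% of the profile differences by transplanting were later. Slide offsets were not settled. The transplanting profile terms with and without the slide as a fixed block correlated at 0.878, but over the 4362 targets chosen without it and on the same samples. With the slide as a fixed block 0 targets passed the adjusted threshold, with standard errors 1.47 times as large at the median. Greater age as the only cause of both shifts is argued against, since the older July plants were earlier (-0.947 h in the targets that differed, -0.404 h over all with a range of at least 1), not later like the older plants of 24 April. An offset in harvest time would move every class of peak hour alike, within a bound of 0.5 h, and the median shifts of the classes spanned 0.521 h by transplanting (95% interval 0.230 to 0.812, from leaving out each of the 13 times) and 0.801 h by sampling date (0.453 to 1.15). Both intervals include the bound, so such an offset cannot be told apart from a shift in the plants. Picking the extreme classes widens these spans. Classes extreme in 1 pair of series differed in the other pair by 0.267 and 0.289 h by transplanting, and by 0.553 and 0.731 h by sampling date. An offset may thus account for part or all of either shift.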

How the results depend on the processing

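The scan day as a block, the main scan day alone, every probe ungrouped, and array and slide both as random blocks were chosen after the data had been seen. Daily change was within 1.5 times its count in 20 of 20 alternatives (49516 to 83453 targets). As a share of the targets tested it ran from 55.1% (no filter on dim probes) to 94.6% (well above background in at least 26 samples). The other counts were within that bound in 17 of 20 alternatives for transplanting, 16 of 20 for sampling date, 11 of 17 for the interaction, 10 of 19 for the second 10:00, 10 of 16 for profiles by transplanting and 11 of 16 for profiles by sampling date.

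With the slide as a fixed block the counts were 91 for transplanting, 339 for sampling date, 606 for the interaction, 21 for the second 10:00, 0 for profiles by transplanting (limma; 8309 targets had an unadjusted p under 0.05) and 2266 by sampling date. Standard errors were 3.06, 5.50, 1.81 and 1.76 times as large for the first 4 of these, since only 3 of the 8 slides held more than 1 series and each series had its first and second 10:00 on different slides. Of the targets that differed in the main results, 80.1, 80.9, 95.1 and 99.6% kept their direction. The correlation of transplanting and sampling date differences turned to -0.341, in a model whose design gives the errors of both contrasts a correlation of -0.83. As a random block in place of the array, the slide gave 2895 for the interaction, 1313 for the second 10:00, and 9471 and 14733 for the profiles, and array and slide together gave 4482 for the interaction.

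Samples taken as independent gave 12965 for the interaction, 502 for the second 10:00, and 15116 and 18505 for the profiles. Without the sampling time as the block that paired the series, 4921 targets differed by transplanting, 606 by sampling date and 143 by the interaction, since the daily change then entered the residual spread. Separate fits to fewer samples gave 11929 by transplanting (the July samples only) and 10088 by sampling date (the 24 April samples only). Ungrouped probes, more in number, gave 30267 by sampling date, 10819 for the interaction, 7710 for the second 10:00, and 6983 and 11696 for the profiles. On the main scan day alone, with fewer samples, the profiles gave 2178 and 3092, and adding a 12-h cosine gave 2311 by transplanting. The second 10:00 gave 2446 under 75th percentile scaling and 2074 without the dye term. Leaving out 1 series gave it 800 (without 68 days) to 3234 (without 61 days), with 1226 without 41 days and 2822 without 48 days. Where no reason is given, the cause was not tested.

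For 40 named probes, 192 of 208 values under alternatives stayed on the same side of the threshold, 16 did not, all with the slide as a fixed block (among the probes printed, all 4 by sampling date, both by profile and transplanting, and eAry2_18260), and none reversed. Gene list alternatives were not run, for want of gene names. Signals near background limit the precision for dim probes: 35239 probes were never well above background.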

Other observations

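The tests of 1 series standing apart, of plant age and of opposite-strand probes in this part were chosen after the results had been seen.

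A range of at least 10-fold was seen for 371 of the 2528 targets peaking at 16:00, 574 of the 5477 at 06:00, 250 of the 2498 at 08:00 and 191 of the 1950 at 04:00. It was seen for 89 of the 2080 targets peaking at 18:00, 28 of the 614 at 02:00 and 20 of the 896 at 00:00. Probes on opposite strands of the same stretch formed 587 pairs in which both were well above background in at least 26 samples. Their profiles over the 52 samples, centred by series, had a median correlation of 0.255 (interquartile range -0.214 to 0.507), with 149 pairs above 0.5 and 91 below -0.5. In 1000 random pairings the median ran from -0.014 to 0.162 (permutation p = 0.001, the smallest these can give), which is consistent with a shared daily course in part of the opposite-strand pairs; labelling of both strands was not tested.

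Differences by transplanting and by sampling date went the same way. A single series standing apart was not settled as the cause. The lower of the 2 correlations between differences from separate pairs of series was 0.303, against 0.083 in simulated data. The simulated targets varied independently, so how high it would come by chance in targets that vary together is not known. The 41-day series may add to the agreement. More targets differed in the comparisons that held it, by transplanting (21572 against 14149) and by sampling date (18599 against 10468). Offsets between arrays or slides are argued against as the whole cause of the transplanting differences alone. With each array that held both plantings left out of the fit, at least 65.7% of the differing targets had the same direction within that array. Targets are not independent replicates, and no array held both sampling dates, so the agreement of both differences was not tested. With the slide as a fixed block their correlation turned negative, in a model whose design gives the errors of both contrasts a correlation of -0.83. Offsets are therefore not settled as a cause of the agreement. Plant age is a candidate explanation, since the older plants changed the same way in both comparisons (correlation of 0.629 across targets). An offset of the 68-day or the 41-day series would also raise that correlation, since both comparisons hold these series with the same sign. The slope of the sampling date difference on the transplanting difference was 0.583, against a ratio of 0.35 between 7 and 20 days, so the weather of the sampling days cannot be told apart from the week of age and may add to it.

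Regroupings of the samples gave the other counts as follows. A chance order of the samples is argued against for daily change, with 55776 targets against 60 in the highest of the other regroupings. These shuffled the times within each series separately, although the series of a date shared their days of harvest. Conditions of an hour on those days are therefore not excluded. For transplanting (25251 against 1) and for sampling date (20112 against 28), labels were exchanged time by time. Such regroupings mix the series, so they cannot tell these differences from a chance offset of a whole series. Each real grouping was the only 1 of 100 with as many. For the second 10:00 the 8 possible regroupings are too few for a share under 0.05; the real count was 4590 and the highest other 126.

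Residuals of consecutive samplings of a series correlated at 0.549 ± 0.171 (SD, n = 24 pairs) on the same array and at 0.054 ± 0.136 (n = 24 pairs) on different arrays. Of the residual variance, 48.0% lay between samples, 42.6% between arrays and 9.45% between slides. For 4 probes with wide ranges, the 4 values at the highest and at the lowest hour (8 groups) were tested for a sample far from the others, and 0 groups passed Dixon's critical ratio.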
